A study of Mus musculus with 8 samples.

How the data were processed

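Liver RNA of 8 libraries, 2 each of the groups NF, HFD, HFD_PA0.25 and HFD_PA1, was measured by sequencing of oligo(dT)-enriched mRNA. Per the labels, RNA was extracted with Trizol and sequenced by BGI. The deposited table gives FPKM for each locus and library. The submitters' processing notes name Bowtie, TopHat, Cufflinks and Cuffdiff, without versions or settings, and the genome build mm10. The notes do not state any scaling between libraries, the annotation or the filters. Some loci in the table run past the ends of GRCm38 chromosomes, so its coordinates are not those of the named build. Coordinates in the text were therefore looked up by gene symbol in GENCODE M21 (GRCm38), where 10027 of the 10889 tested genes (92.1%) were found.

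All 8 value columns were used. The 4 groups were taken from the sample labels and the column names. The columns carry library numbers 0 and 1 and the labels 1 and 2, which cannot be tied to each other, so libraries are named by the numbers in the table. The table holds 25287 loci, of which 1300 carry no symbol; these held 13.4% to 33.6% of the summed FPKM of a library and were left out of the main test. Of the 23987 named loci, 642 join several genes, 822 share a symbol with another locus and 7229 were at 0 in all 8 libraries. Where copies are near identical (Mup, H2, Gsta, Gstm, Cyp2b and Serpina1 genes) reads can be shared between them. Genes listed at 0 are given with the value of each library, with no mean and no fold.

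Named loci with FPKM of at least 1 in at least 2 libraries were tested, 10889 in all, 32 of them at 0 in 1 or more libraries. Values were taken as log2(FPKM + 1), which understates differences at low levels. limma 3.58.1 in R 4.3.3 was fitted to all 8 libraries at once with the group means as terms, with 4 residual and 5.93 prior degrees of freedom from empirical Bayes moderation with a trend. Tests were two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The planned comparisons were HFD against NF, HFD_PA0.25 against HFD, HFD_PA1 against HFD and HFD_PA1 against HFD_PA0.25; both PA groups against NF were added after the data were seen. A fit with library number as a block was not possible, because nothing states what the numbers pair.

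Groups of genes were tested with camera in limma, which compares the members with all other tested genes, at a preset correlation between genes of 0.01 and again with the correlation estimated per list. Adjustment was over the 24 lists with at least 5 tested members. The 25 lists, fixed with the tests and most alternatives before the data were examined, were fatty acid synthesis, cholesterol synthesis and uptake, fatty acid oxidation and PPAR-alpha targets, lipid droplets, bile acids, glucose, xenobiotic metabolism, NRF2, interferon response, acute phase, endoplasmic reticulum and integrated stress, circadian clock, male-biased and female-biased liver genes, cell cycle, immediate early genes, and antigen presentation. Markers of stellate cells and matrix, macrophages, lymphocytes, endothelium, bile duct, erythroid cells and neutrophils, adipose tissue and exocrine pancreas completed them. Members called over all tested genes were counted, and so were members called when adjusted over the list alone.

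Genes are named by a rule fixed at the same time. Per comparison it takes up to 8 genes with the largest positive and 8 with the largest negative log2 difference among those that passed, had a mean of at least 2 FPKM in the higher group and did not overlap between the groups. Model names and pseudogenes were skipped. Per list it adds up to 4 members with the smallest unadjusted p. A gene named in 1 comparison may be given in the others. Some genes picked this way are not reported here. The STAT5 targets in the closing section were chosen after the data were seen.

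To set each PA comparison beside the diet comparison, the log2 differences were correlated across genes. Then 100 simulated data sets with the same spread and no PA effect gave the value that the shared HFD libraries produce alone. Genes were drawn independently, so shifts shared by many genes of a library are absent from the simulated values and their SD. Alternatives fixed beforehand were a pseudocount of 0.1, a filter at any value above 0 or at 5 FPKM in 2 libraries, moderation without trend, quantile normalization, median-ratio scaling, a fit of only the groups compared, and leaving out each library. Alternatives added after the data were seen were including loci without a symbol, leaving out genes at 0 in any library, only loci naming 1 protein-coding gene (9744), removing from each library a trend with transcript length and GC content (spline with 4 degrees of freedom), taking 1 HFD library for the diet comparison and the other for the PA comparison, and, for the correlation, only genes that share no 30-base word with transcripts of another gene in GENCODE M21 (3248).

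The fits were tested on simulated data with 200 changed genes among 10691 to 10716 that passed the filter. At a log2 difference of 0.5, 65.7% to 83.6% of the changed genes were called, at 1 95.5% to 100%, and at 2 100%, with 10 to 14 false calls per comparison. A shifted list was called in each comparison and none (0) of 20 unshifted lists was. Genes were simulated as independent, so false calls from correlated members of a list were not tested. Read counts were not used here, so no counting intervals are given and the depth of the libraries is not known here. Body weights were not analysed here.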

Results

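Poly(A)-selected liver RNA was sequenced from male C57BL/6J mice fed 4 diets, with 2 libraries per diet and 8 in all. NF mice received standard chow, and HFD mice received a high-fat chow (lard at 15%, sugar at 10% and powdered egg yolk at 3%). HFD_PA0.25 and HFD_PA1 mice received that high-fat chow with 0.25% or 1% of a soybean PA extract, from the re-grouping in week 12 onward. High-fat feeding had by then lasted 11 weeks. Mice were 3 weeks old at the start, with 1 week of acclimation. The labels do not expand the abbreviation PA. The series title places the work in the prevention of diet-induced obesity. The submitters describe feeding groups of 7 (HFD), 8 (HFD_PA0.25) and 8 (HFD_PA1) mice and 100 mg of liver for each group. Nothing states that the 2 libraries of a group came from separate animals, so every p-value measures the spread between these libraries only. The libraries carry the numbers 0 and 1 in the table of values.

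The values are FPKM (fragments per kilobase of transcript, scaled to library depth), and read counts were not used here. Summed over all loci, FPKM ran from 779711 to 1098856 per library. Between 10327 and 10532 named genes reached 1 FPKM in a library. The 2 libraries of a group correlated across genes at r = 0.994 to 0.996, over genes that are not independent replicates. The SD of the log2 difference between them was 0.231 in NF, 0.192 in HFD, 0.192 in HFD_PA0.25 and 0.203 in HFD_PA1. Of 23987 named loci, 10889 passed the filter and were tested. Albumin (Alb) and the cholesterol synthesis gene Hmgcs1 were listed at 0 in all 8 libraries. The joined locus of Apoe, the main lipoprotein ligand, and Tomm40 was given as 20029.6 and 25262.3 FPKM in NF and listed at 0 in the other 6. A value of 0 may stand for no expression or for a locus that the quantification did not measure, which was not tested, so no effect of diet is read from these loci. The joined locus still met the filter through its NF values. It therefore stayed among the 10889 tested genes and enters the correlations across genes given below.

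NF and HFD_PA1 libraries stood apart from HFD and HFD_PA0.25 libraries in several measures. Loci without a gene symbol held 30.04% and 33.6% of the summed FPKM in NF and 22.8% and 20.2% in HFD_PA1. In HFD they held 13.4% and 15.3%, and in HFD_PA0.25 13.7% and 17.5%. On the first principal component, with 51.3% of the variance, HFD_PA1 lay between NF and the other groups, nearer to HFD: NF libraries lay at 29.65 and 25.65, HFD_PA1 at 3.15 and 1.14, HFD at -12.44 and -12.80, and HFD_PA0.25 at -17.55 and -16.80. The second component, with 16.3%, set HFD_PA1, at -16.94 and -15.16, apart from NF, at 6.52 and 7.39. A set of 71 genes separated NF and HFD_PA1 from the other libraries with no overlap and by more than 2-fold between the means of the paired groups, against 18 and 20 genes for the other ways to pair the groups. In 28 of them NF and HFD_PA1 each differed over 2-fold from both other groups, against 2 and 4 genes. The 71 held 8 of 50 tested pseudogenes, the 28 held 6, and the other pairings held 0. The largest FPKM step of which all values of the 4 unnamed 160-base loci were whole multiples was taken per library. The tolerance was 2% of a step at low multiples and wider at high ones. This step was 437 to 1218 in NF and HFD_PA1 and 81.7 to 112.5 in the other libraries. Comparisons of HFD with NF, HFD_PA1 with HFD, and HFD_PA1 with HFD_PA0.25 cross this split, and in those a batch of that kind and the diet cannot be told apart by the comparison alone. HFD_PA0.25 against HFD and HFD_PA1 against NF lie within it. HFD_PA1 against NF called 357 of the genes higher and 535 of those lower in HFD than in NF the same way, and 12 and 9 the other way. A batch that shifted NF and HFD_PA1 alike would not give those shared changes. A batch graded from NF through HFD_PA1 to the other libraries could, as the share of loci without a symbol was graded, and was not tested. With a different NF library in each comparison, 172 and 283 genes were shared the same way and 6 and 6 the other way (NF library 0 in HFD against NF), or 207 and 330 against 7 and 4 (NF library 1).

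HFD against NF asked what the high-fat chow changed in the liver. Fgf21, a hormone that the liver releases in fasting and nutrient stress, rose from 2.72 ± 0.354 FPKM in NF to 78.3 ± 0.431 in HFD (mean ± SD, n = 2 libraries per group here and throughout; log2 difference 4.42 on the log2(FPKM + 1) scale, adjusted p = 7.27e-09). Asns, asparagine synthetase, rose from 2.33 ± 0.475 to 28.05 ± 2.39 FPKM and Psat1, an enzyme of serine synthesis, from 0.359 ± 0.07796 to 9.82 ± 0.928. Cidec, a protein that fuses lipid droplets, rose from 1.74 ± 0.224 to 12.00 ± 0.694 FPKM. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell from 72.2 ± 7.89 to 18.6 ± 1.66 FPKM (log2 difference -1.90, adjusted p = 1.37e-05). The male-biased major urinary protein gene Mup1 fell from 2024 ± 348 to 89.8 ± 13.7 FPKM (log2 difference -4.48, adjusted p = 3.38e-07), at a locus whose reads can be shared with near-identical Mup copies. In GRCm38, Fgf21 is a protein-coding gene at 45613886 to 45615490 on chromosome 7, Asns lies at 7675169 to 7693254 on chromosome 6 and Cyp7a1 at 6265612 to 6275633 on chromosome 4.

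Genes of endoplasmic reticulum and integrated stress were higher in HFD, with 12 of 18 tested members higher and 0 lower, 13 and 0 adjusted over the list alone (camera adjusted p = 5.15e-07; adjusted p = 0.268 with an estimated correlation). Besides Asns, Manf, a secreted factor of the stressed reticulum, rose from 25.3 ± 1.12 to 49.6 ± 3.07 FPKM, Creld2, a chaperone of the same compartment, from 10.6 ± 0.895 to 19.5 ± 0.194, and Trib3, a pseudokinase induced by ATF4, from 9.71 ± 1.08 to 19.1 ± 1.59. The stress-induced chromatin protein gene Nupr1, named for the size of its change, rose from 1.09 ± 0.07595 to 21.4 ± 2.75 FPKM (log2 difference 3.42, adjusted p = 3.38e-07). Lipid droplet, lipid uptake and storage genes were higher on balance, with 11 of 19 tested members higher and 4 lower, 13 and 5 adjusted over the list alone (camera adjusted p = 0.00465; adjusted p = 0.334 with an estimated correlation). Alongside Cidec, G0s2, an inhibitor of triglyceride lipase, rose from 200.2 ± 9.14 to 309.9 ± 7.601 FPKM, whereas Fitm2, which helps droplets bud, fell from 22.4 ± 1.94 to 11.3 ± 0.0419.

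Bile acid synthesis and transport genes were lower, with 2 of 17 tested members higher and 10 lower, 2 and 10 adjusted over the list alone (camera adjusted p = 0.00882; adjusted p = 0.618 with an estimated correlation). Cyp8b1, which sets the share of cholic acid, fell from 202 ± 2.25 to 104 ± 3.59 FPKM and Cyp7b1, of the alternative pathway, from 278 ± 35.6 to 111 ± 3.33. Nr0b2, a repressor of bile acid synthesis, rose from 24.3 ± 3.37 to 64.01 ± 0.809 FPKM. Male-biased liver genes were lower, with 1 of 17 tested members higher and 14 lower, 1 and 14 adjusted over the list alone (camera adjusted p = 5.15e-07; adjusted p = 0.268 with an estimated correlation) and a median log2 difference of -0.78. Serpina1e, an alpha-1-antitrypsin copy at 103946931 to 103958975 on chromosome 12, fell from 8303 ± 70.9 to 1986 ± 20.8 FPKM, and the steroid reductase gene Hsd3b5 from 239 ± 7.36 to 92.7 ± 6.45. Female-biased liver genes were higher, with 5 of 6 tested members higher and 0 lower, 5 and 0 adjusted over the list alone (camera adjusted p = 2.47e-06; adjusted p = 0.193 with an estimated correlation) and a median of 1.25. The joined locus of the steroid hydroxylases Cyp2b13 and Cyp2b9 rose from 0.0383 ± 0.00714 to 14.6 ± 1.24 FPKM, and Cyp17a1, of androgen synthesis, from 0.535 ± 0.167 to 4.39 ± 0.2798. All libraries were from male mice by the labels.

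Antigen presentation genes were lower in HFD than in NF, with 0 of 12 tested members higher and 7 lower, 0 and 7 adjusted over the list alone (camera adjusted p = 0.0153; adjusted p = 0.334 with an estimated correlation). H2-DMb1, which loads peptides on class II molecules, fell from 6.998 ± 0.328 to 2.24 ± 0.224 FPKM, and Cd74, the class II invariant chain in a locus joined with Mir5107, from 107 ± 9.45 to 71.7 ± 2.41. Erythroid and neutrophil markers were higher, with 4 of 6 tested members higher and 0 lower, 4 and 0 adjusted over the list alone (camera adjusted p = 0.00465; adjusted p = 0.334 with an estimated correlation). The neutrophil alarmins S100a8 and S100a9 rose from 8.65 ± 1.01 to 23.2 ± 2.19 and from 3.12 ± 0.357 to 12.8 ± 2.66 FPKM. Interferon response genes were lower, with 0 of 24 tested members higher and 8 lower, 0 and 8 adjusted over the list alone (camera adjusted p = 0.0393; adjusted p = 0.675 with an estimated correlation). The interferon regulator Irf7 fell from 29.6 ± 0.191 to 23.5 ± 0.0208 FPKM. The interferon call was lost without HFD library 0 (adjusted p = 0.102), without NF library 0 (0.104), with a filter at 5 FPKM (0.104) and over loci naming 1 protein-coding gene (0.0504), in a range of 0.00745 to 0.104 over the alternatives.

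Immediate early and heat shock genes were higher on balance, with 5 of 16 tested members higher and 2 lower, 7 and 2 adjusted over the list alone (camera adjusted p = 0.0179; adjusted p = 0.618 with an estimated correlation). Egr1, a growth-factor-induced transcription factor, rose from 3.24 ± 0.886 to 11.9 ± 2.07 FPKM and the small heat shock protein gene Hspb1 from 29.7 ± 5.61 to 47.9 ± 5.78, whereas Gadd45g, a growth arrest gene, fell from 14.6 ± 3.26 to 8.19 ± 0.627. This call was lost without NF library 0 (adjusted p = 0.104) and with a filter at 5 FPKM (0.0635), in a range of 0.00357 to 0.104. Lymphocyte markers were higher, with 3 of 6 tested members higher and 0 lower, 3 and 0 adjusted over the list alone (camera adjusted p = 0.0176; adjusted p = 0.334 with an estimated correlation). Jchain, the joining chain of secreted antibodies, rose from 3.296 ± 0.478 to 9.08 ± 1.95 FPKM and the B cell receptor gene Cd79a from 0.918 ± 0.0886 to 2.49 ± 0.708. The lymphocyte call was lost without HFD library 1 (adjusted p = 0.0582) and with quantile normalization (0.0566), in a range of 0.00297 to 0.0582.

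Single genes moved in lists that did not pass as a whole in HFD against NF. Saa1, an acute phase protein gene, fell from 245 ± 0.4596 to 85.8 ± 13.5 FPKM in a list with 4 members higher and 5 lower (adjusted p = 0.656). Igfbp1, a fasting-induced binding protein, fell from 26.05 ± 1.71 to 9.27 ± 0.171 FPKM in the glucose and glycogen list (adjusted p = 0.0924), and Por, the electron donor of cytochromes P450, from 284 ± 5.97 to 129 ± 2.11 in the xenobiotic metabolism list (0.0826). The scavenger receptor gene Marco rose from 9.61 ± 0.743 to 39.00 ± 3.15 FPKM, whereas Mpeg1, a pore-forming macrophage protein, fell from 23.4 ± 2.099 to 9.46 ± 0.723, in the macrophage and Kupffer cell list (adjusted p = 0.0878). Mt2, a metallothionein, rose from 12.9 ± 1.25 to 52.01 ± 4.39 FPKM in the NRF2 list (0.0844). Fatty acid synthesis (adjusted p = 0.426), cholesterol synthesis (0.426) and fatty acid oxidation (0.113) did not pass. Nor did circadian clock (0.269), cell cycle (0.197), extracellular matrix (0.543), endothelial (0.495), bile duct (0.0824) and adipose markers (0.819). With the length and GC trend removed, xenobiotic metabolism (camera adjusted p = 0.00148) and macrophage markers (0.0109) passed, with medians of -0.30 and -0.32. Xenobiotic metabolism also passed over loci naming 1 protein-coding gene (0.0152). A filter at any value above 0 brought xenobiotic metabolism (0.0257), bile duct markers (0.0247) and glucose (0.0328) under 0.05. A filter at 5 FPKM did so for macrophage markers (0.0422). Bile duct (0.0194) and macrophage markers (0.0125) passed without HFD library 1. So did xenobiotic metabolism (0.00939) without NF library 1, and NRF2 (0.029) without NF library 0. Median, mean and test differed in sign for fatty acid synthesis (median -0.08, mean 0.05, test higher), acute phase (0.08, -0.02, higher) and adipose markers (-0.15, 0.14, lower). Exocrine pancreas markers had 2 tested members, too few for a test. Cela1, which liver also expresses, stood at 90.8 ± 3.15 FPKM in NF and 57.2 ± 1.27 in HFD.

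Between HFD and NF, 3496 of 10889 genes passed in limma, 1401 higher and 2095 lower in HFD; 4756 had an unadjusted p under 0.05. Of the called genes, 104 were over 2-fold higher and 114 over 2-fold lower, and in all 3496 the 2 libraries of each group did not overlap. Among all tested genes that share was 67.7%, against 33.3% by chance. Hamp2, a paralog of the iron hormone hepcidin, stood at 34.6 ± 5.45 FPKM in NF and 339 ± 18.6 in HFD and lost its call without any single library of the 2 groups (adjusted p = 0.0841 and 0.0972 without HFD library 0 and 1, 0.099 and 0.058 without NF library 0 and 1; range over the alternatives 6.59e-07 to 0.101). With median-ratio scaling 1764 were higher and 1792 lower (49.6% higher), and with quantile normalization 1729 and 1778 (49.3%), against 40.1% in the main test. The count was 2126 without HFD library 0, 1857 without HFD library 1 and 1886 without NF library 0. This comparison crosses the split: transcripts under 1500 bases had a median log2 difference of 0.14 and those over 5000 bases -0.21.

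HFD_PA0.25 against HFD asked what the lower PA level changed on the high-fat chow. Interferon-induced genes rose: Igtp, a GTPase of cell-autonomous immunity at 58199556 to 58207591 on chromosome 11, went from 12.99 ± 1.79 FPKM in HFD to 73.9 ± 10.5 in HFD_PA0.25 (log2 difference 2.42, adjusted p = 1.06e-05), with 18.5 ± 0.0497 in NF. Tap1, which carries peptides to class I molecules, rose from 10.9 ± 0.611 to 26.6 ± 0.129 FPKM (log2 difference 1.22, adjusted p = 2.07e-05). Thrsp, a lipogenic nuclear protein gene at 97412938 to 97417730 on chromosome 7, fell from 626 ± 31.9 to 215 ± 31.4 FPKM (log2 difference -1.55, adjusted p = 2.07e-05). Bhmt, which remethylates homocysteine with betaine and lies at 93616675 to 93637961 on chromosome 13, fell from 712 ± 40.3 to 177 ± 17.2 FPKM, with 1293 ± 84.5 in NF. The neutrophil chemokine gene Cxcl1 fell from 22.6 ± 5.07 to 4.24 ± 0.146 FPKM (log2 difference -2.15, adjusted p = 1.93e-05).

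Interferon response genes were higher in HFD_PA0.25 than in HFD, with 17 of 24 tested members higher and 0 lower, 21 and 0 adjusted over the list alone (camera adjusted p = 3.14e-22; adjusted p = 0.121 with an estimated correlation) and a median log2 difference of 0.64. Irf7 rose from 23.5 ± 0.0208 to 46.1 ± 1.24 FPKM. Outside the list, the interferon-induced GTPase genes Irgm2 and Gbp6 rose from 8.78 ± 1.47 to 32.5 ± 1.63 and from 2.43 ± 0.241 to 9.03 ± 1.37 FPKM. Antigen presentation genes were higher, with 11 of 12 tested members higher and 0 lower, 11 and 0 adjusted over the list alone (camera adjusted p = 1.04e-15; adjusted p = 0.0772 with an estimated correlation) and a median of 0.82. Besides Tap1, the class II chain gene H2-Aa rose from 32.7 ± 1.51 to 64.4 ± 2.92 FPKM, the Cd74 locus from 71.7 ± 2.41 to 136 ± 2.45 and H2-DMb1 from 2.24 ± 0.224 to 7.05 ± 0.739; reads of H2 genes can be shared between copies. Macrophage and Kupffer cell markers were higher, with 6 of 17 tested members higher and 1 lower, 8 and 2 adjusted over the list alone (camera adjusted p = 0.000737; adjusted p = 0.507 with an estimated correlation). Clec4f, a lectin of Kupffer cells, rose from 39.04 ± 1.96 to 61.4 ± 0.0623 FPKM. The macrophage call was lost without HFD library 0 (adjusted p = 0.0999), in a range of 1.04e-06 to 0.0999 over the alternatives. Lymphocyte markers were higher, with 2 of 6 tested members higher and 0 lower, 2 and 0 adjusted over the list alone (camera adjusted p = 0.00575; adjusted p = 0.258 with an estimated correlation). Jchain stood at 9.08 ± 1.95 FPKM in HFD and 18.6 ± 4.88 in HFD_PA0.25, called with all libraries but not without HFD library 1 (adjusted p = 0.106) or HFD_PA0.25 library 0 (0.0723). The lymphocyte call was lost without HFD library 0 (adjusted p = 0.119) and HFD_PA0.25 library 1 (0.0591), in a range of 0.000162 to 0.119.

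Fatty acid synthesis genes were lower with the lower PA level, with 0 of 19 tested members higher and 7 lower, 0 and 8 adjusted over the list alone (camera adjusted p = 3.03e-06; adjusted p = 0.507 with an estimated correlation). Besides Thrsp, the liver pyruvate kinase gene Pklr fell from 141 ± 3.38 to 91.8 ± 1.56 FPKM and Aacs, which activates acetoacetate for lipid synthesis, from 43.3 ± 3.21 to 29.7 ± 0.004596. Genes of xenobiotic metabolism were lower, with 0 of 16 tested members higher and 7 lower, 1 and 8 adjusted over the list alone (camera adjusted p = 0.00137; adjusted p = 0.507 with an estimated correlation). The Cyp2b13 and Cyp2b9 locus fell from 14.6 ± 1.24 to 2.75 ± 0.152 FPKM, and Cyp2b10, a target of the receptor CAR, from 11.00 ± 0.418 to 6.59 ± 0.242. Female-biased genes, a list that holds the same joined locus, were lower, with 0 of 6 tested members higher and 4 lower, 1 and 5 adjusted over the list alone (camera adjusted p = 0.000123; adjusted p = 0.121 with an estimated correlation). Cyp2a22 fell from 2.99 ± 0.366 to 0.497 ± 0.0628 FPKM. Male-biased genes were higher on balance, with 5 of 17 tested members higher and 1 lower, 7 and 3 adjusted over the list alone (camera adjusted p = 0.0244; adjusted p = 0.507 with an estimated correlation). Serpina1e rose from 1986 ± 20.8 to 4717 ± 13.5 FPKM and Hsd3b5 from 92.7 ± 6.45 to 144 ± 2.93. The male-biased call was lost without HFD library 1 (adjusted p = 0.0556), in a range of 0.000931 to 0.0556. Clock genes were lower, with 0 of 16 tested members higher and 7 lower, 0 and 7 adjusted over the list alone (camera adjusted p = 0.000275; adjusted p = 0.258 with an estimated correlation). Ciart, a clock repressor, fell from 14.1 ± 0.1601 to 6.65 ± 0.809 FPKM and Bhlhe40, in a locus joined with a Rik model, from 46.5 ± 1.73 to 31.9 ± 1.03.

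Other genes moved with the lower PA level in lists that did not pass. The antioxidant genes Mt2 and Gstm2 fell from 52.01 ± 4.39 to 18.4 ± 0.817 and from 96.6 ± 3.46 to 38.98 ± 2.62 FPKM in the NRF2 list (adjusted p = 0.0535). Reads of Gstm genes can be shared. Fgf21 fell from 78.3 ± 0.431 to 45.9 ± 6.27 FPKM in the fatty acid oxidation list (0.147). Igfbp1 rose from 9.27 ± 0.171 to 27.9 ± 0.7803 FPKM in the glucose list (0.964), and Cyp8b1 from 104 ± 3.59 to 147 ± 5.15 in the bile acid list (0.226). G0s2 fell from 309.9 ± 7.601 to 193 ± 17.8 FPKM in the lipid droplet list (0.0837), and Dusp1, an immediate early phosphatase gene, from 19.4 ± 0.267 to 6.67 ± 0.326 in the immediate early list (0.905). Cholesterol synthesis (adjusted p = 0.958), acute phase (0.177) and endoplasmic reticulum stress (0.209) did not pass. Nor did cell cycle (0.964), extracellular matrix (0.722), endothelial (0.0837), bile duct (0.958), erythroid and neutrophil (0.561) and adipose markers (0.177). A filter at any value above 0 brought endothelial markers under 0.05 (camera adjusted p = 0.031). NRF2 passed over loci naming 1 protein-coding gene (0.0484). Leaving out HFD library 1 brought acute phase (0.0282) and NRF2 (0.039) under 0.05. HFD_PA0.25 library 1 did so for NRF2 (0.0314) and endothelial markers (0.00953), HFD library 0 for endothelial markers (0.0024) and HFD_PA1 library 1 for NRF2 (0.0491). All of these were lower in HFD_PA0.25. Signs differed for cholesterol synthesis (median -0.04, mean 0.01, test lower), glucose (-0.04, 0.03, higher), cell cycle (-0.06, 0.01, higher) and immediate early genes (0.00, -0.12, lower).

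Between HFD_PA0.25 and HFD, 680 genes passed in limma, 295 higher and 385 lower with PA; 2207 had an unadjusted p under 0.05. Over 2-fold were 32 higher and 23 lower, and 49.6% of tested genes did not overlap between the groups against 33.3% by chance. Mup19 was given as 56.7 and 54.2 FPKM in HFD_PA0.25 and listed at 0 in the other 6 libraries, where a locus that was not measured cannot be told from no expression. The count depended on single libraries, with 217 without HFD library 0, 219 without HFD library 1, 330 without HFD_PA0.25 library 0 and 296 without HFD_PA0.25 library 1. It was 372 with a filter at any value above 0 and 427 in a fit of these 4 libraries alone.

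HFD_PA1 against HFD asked what the higher PA level changed on the high-fat chow. Fgf21 fell from 78.3 ± 0.431 FPKM in HFD to 16.2 ± 0.0724 in HFD_PA1 (log2 difference -2.21, adjusted p = 3.2e-06), a level above the 2.72 ± 0.354 of NF. Thrsp fell from 626 ± 31.9 to 188 ± 8.17 FPKM (log2 difference -1.73, adjusted p = 1.12e-05), a level under the 432 ± 17.5 of NF. The Kupffer cell scavenger receptor gene Marco, at 120474538 to 120505024 on chromosome 1, fell from 39.00 ± 3.15 to 8.12 ± 0.326 FPKM, with 9.61 ± 0.743 in NF (log2 difference -2.13, adjusted p = 3.2e-06). Saa1, at 46740497 to 46742980 on chromosome 7, rose from 85.8 ± 13.5 to 268 ± 15.1 FPKM, with 245 ± 0.4596 in NF (log2 difference 1.64, adjusted p = 1.64e-05). Mup1 rose from 89.8 ± 13.7 to 597 ± 139 FPKM (log2 difference 2.71, adjusted p = 3.15e-05), with the shared reads of Mup copies as a limit. Fgf21, Marco, Saa1 and Mup1 are among the 71 genes that separated NF and HFD_PA1 from the other libraries.

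Fatty acid synthesis genes were lower in HFD_PA1 than in HFD, with 0 of 19 tested members higher and 12 lower, 1 and 14 adjusted over the list alone (camera adjusted p = 6.11e-09; adjusted p = 0.657 with an estimated correlation) and a median log2 difference of -0.38. Fasn, the fatty acid synthase, fell from 50.2 ± 1.03 to 27.3 ± 1.35 FPKM, Aacs from 43.3 ± 3.21 to 22.3 ± 0.624 and Pklr from 141 ± 3.38 to 85.9 ± 3.51. NRF2 and antioxidant genes were lower on balance, with 1 of 23 tested members higher and 9 lower, 3 and 11 adjusted over the list alone (camera adjusted p = 5.13e-06; adjusted p = 0.527 with an estimated correlation). The glutathione transferase genes Gstm3 and Gsta2 fell from 153 ± 0.442 to 52.3 ± 3.13 and from 92.03 ± 5.34 to 40.1 ± 2.801 FPKM, in families whose reads can be shared. Acute phase and inflammation genes were higher, with 12 of 21 tested members higher and 0 lower, 13 and 1 adjusted over the list alone (camera adjusted p = 2.1e-06; adjusted p = 0.601 with an estimated correlation). Saa1 led this list. Itih4, a plasma protein of the acute phase, stood at 445 ± 36.7 FPKM in HFD and 602 ± 6.500 in HFD_PA1, called with all libraries but not without HFD library 1 (adjusted p = 0.0658) or HFD_PA1 library 0 (0.0582).

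Antigen presentation genes were higher with the higher PA level, with 6 of 12 tested members higher and 0 lower, 7 and 0 adjusted over the list alone (camera adjusted p = 1.05e-05; adjusted p = 0.527 with an estimated correlation). The Cd74 locus rose from 71.7 ± 2.41 to 139 ± 10.5 FPKM, H2-Aa from 32.7 ± 1.51 to 56.8 ± 4.52 and the class II chain gene H2-Ab1 from 40.7 ± 2.77 to 80.5 ± 10.4, with H2 reads shared between copies. Interferon response genes were higher on balance, with 7 of 24 tested members higher and 1 lower, 11 and 1 adjusted over the list alone (camera adjusted p = 0.00291; adjusted p = 0.748 with an estimated correlation). Oas2, a sensor of viral RNA, stood at 0.968 ± 0.114 FPKM in HFD and 2.03 ± 0.194 in HFD_PA1, called with all libraries but not without HFD library 0 (adjusted p = 0.0555) or HFD_PA1 library 0 (0.0826). A filter at 5 FPKM ended the interferon call (adjusted p = 0.111), in a range of 0.000613 to 0.111. Macrophage and Kupffer cell markers were higher on balance, against the fall of Marco, with 8 of 17 tested members higher and 2 lower, 9 and 2 adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.748 with an estimated correlation). Clec4f rose from 39.04 ± 1.96 to 63.6 ± 7.57 FPKM and Mpeg1 from 9.46 ± 0.723 to 16.5 ± 2.51. This call was lost without HFD library 0 (adjusted p = 0.196) and HFD_PA1 library 0 (0.0873), in a range of 0.000214 to 0.196. Endothelial markers were higher, with 3 of 12 tested members higher and 0 lower, 3 and 0 adjusted over the list alone (camera adjusted p = 0.0137; adjusted p = 0.748 with an estimated correlation). Lyve1, a hyaluronan receptor of liver sinusoids, stood at 1.99 ± 0.423 FPKM in HFD and 3.32 ± 0.177 in HFD_PA1, called with all libraries but not without HFD library 1 (adjusted p = 0.133), HFD_PA1 library 0 (0.101) or HFD_PA1 library 1 (0.105). The endothelial call was lost without HFD library 0 (adjusted p = 0.221) and HFD_PA1 library 0 (0.0988), in a range of 0.000109 to 0.221.

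In lists that did not pass between HFD_PA1 and HFD, G0s2 fell from 309.9 ± 7.601 to 165 ± 6.33 FPKM and Cidec from 12.00 ± 0.694 to 3.02 ± 0.0124 among lipid droplet genes (adjusted p = 0.185). Abcg8, a sterol exporter of the canaliculus, rose from 38.6 ± 1.24 to 61.4 ± 2.01 FPKM among bile acid and transport genes (0.193). G6pc, which releases free glucose, fell from 62.5 ± 0.603 to 40.6 ± 1.83 FPKM among glucose genes (0.246), and Mvd, of the mevalonate pathway, from 29.6 ± 2.202 to 20.4 ± 0.1697 among cholesterol genes (0.0854). Serpina1e rose from 1986 ± 20.8 to 5087 ± 38.2 FPKM whereas Cyp4a12a, a male-biased fatty acid hydroxylase gene, fell from 105 ± 8.75 to 59.3 ± 1.58 in the male-biased list (0.664). Dusp1 fell from 19.4 ± 0.267 to 7.15 ± 0.242 FPKM among immediate early genes (0.0854). Cyp7a1 stood at 18.6 ± 1.66 FPKM in HFD and 15.4 ± 2.16 in HFD_PA1. Fatty acid oxidation (adjusted p = 0.193), xenobiotic metabolism (0.619) and endoplasmic reticulum stress (0.64) did not pass. Nor did circadian clock (0.394), female-biased genes (0.689), cell cycle (0.0725), extracellular matrix (0.296), lymphocyte (0.539), bile duct (0.193), erythroid and neutrophil (0.459) and adipose markers (0.689). With the length and GC trend removed, cholesterol synthesis (camera adjusted p = 0.0107) and fatty acid oxidation (0.0361) passed. Quantile normalization brought fatty acid oxidation (0.0198), cell cycle (0.0329) and bile acid genes (0.0289) under 0.05. Cell cycle passed without the trend in the test (0.0306) and with a filter at any value above 0 (0.00318). Cholesterol synthesis passed with median-ratio scaling (0.0499), immediate early genes with a filter at 5 FPKM (0.0461). Leaving out HFD library 1 brought cholesterol synthesis (0.00329), cell cycle (0.0159) and bile duct markers (0.042) under 0.05, all lower in HFD_PA1. HFD library 0 did so for extracellular matrix (0.0331, higher) and HFD_PA1 library 1 for immediate early genes (0.00419, lower). Signs differed for xenobiotic metabolism (median 0.02, mean -0.03, test lower), female-biased genes (-0.06, 0.06, higher) and adipose markers (-0.06, 0.06, lower).

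Between HFD_PA1 and HFD, 1372 genes passed in limma, 717 higher and 655 lower with PA; 3217 had an unadjusted p under 0.05. Over 2-fold were 23 higher and 42 lower, and 62.0% of tested genes did not overlap against 33.3% by chance. Hamp2, at 33.9 ± 10.9 FPKM in HFD_PA1, lost its call (adjusted p = 0.0457) without any single library of HFD (0.146 without library 0, 0.166 without library 1), HFD_PA1 (0.223, 0.106) or NF (0.0516, 0.0507), in a range of 2.61e-05 to 0.223. The count was 405 without HFD library 0, 388 without HFD library 1, 227 without HFD_PA1 library 0, 499 without HFD_PA1 library 1 and 749 with a filter at any value above 0. With median-ratio scaling 633 were higher and 866 lower, a share of 42.2% higher against 52.3% in the main test. This comparison crosses the split: transcripts under 1500 bases had a median log2 difference of -0.15 and those over 5000 bases 0.14.

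HFD_PA1 against HFD_PA0.25 asked how the PA levels differed. Igtp was lower at the higher level, with 19.1 ± 3.21 FPKM in HFD_PA1 against 73.9 ± 10.5 in HFD_PA0.25 (log2 difference -1.90, adjusted p = 3.83e-05). Cxcl1 was higher, with 24.03 ± 1.97 against 4.24 ± 0.146 FPKM (log2 difference 2.25, adjusted p = 1.26e-05), and so was Phlda1, a pleckstrin homology protein gene, with 103 ± 4.68 against 22.5 ± 0.0436 (log2 difference 2.15, adjusted p = 2.12e-06). Fgf21 was lower at the higher level, with 16.2 ± 0.0724 against 45.9 ± 6.27 FPKM, and so was Igfbp1, with 7.096 ± 1.16 against 27.9 ± 0.7803. The joined Cyp2b13 and Cyp2b9 locus was higher, with 22.8 ± 1.04 against 2.75 ± 0.152 FPKM (log2 difference 2.67, adjusted p = 4.66e-07).

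Interferon response genes were lower at the higher PA level than at the lower, with 0 of 24 tested members higher and 10 lower, 1 and 14 adjusted over the list alone (camera adjusted p = 6.9e-09; adjusted p = 0.335 with an estimated correlation) and a median log2 difference of -0.35. The immunoproteasome genes Psmb8 and Psmb9 stood at 48.2 ± 1.14 and 38.1 ± 2.55 FPKM in HFD_PA1 against 79.3 ± 3.07 and 69.8 ± 2.84 in HFD_PA0.25, both called lower. Antigen presentation genes were lower, with 0 of 12 tested members higher and 4 lower, 1 and 6 adjusted over the list alone (camera adjusted p = 0.00125; adjusted p = 0.335 with an estimated correlation). Tap1 was called lower, at 13.1 ± 0.373 against 26.6 ± 0.129 FPKM, and Tap2, its partner, at 13.6 ± 0.0169 against 21.4 ± 0.7097. Acute phase and inflammation genes were higher, with 12 of 21 tested members higher and 0 lower, 14 and 0 adjusted over the list alone (camera adjusted p = 9.28e-07; adjusted p = 0.335 with an estimated correlation) and a median of 0.42. Saa1 was called higher, at 268 ± 15.1 against 83.2 ± 3.01 FPKM, as was Socs3, a feedback inhibitor of cytokine signals, at 9.12 ± 0.259 against 4.302 ± 0.184. Clock genes were higher, with 9 of 16 tested members higher and 1 lower, 10 and 1 adjusted over the list alone (camera adjusted p = 0.000484; adjusted p = 0.335 with an estimated correlation). Ciart was called higher, at 15.3 ± 0.943 against 6.65 ± 0.809 FPKM, and the clock output factor gene Hlf at 14.02 ± 0.321 against 8.46 ± 0.745.

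Endothelial markers were higher at the higher PA level, with 8 of 12 tested members higher and 0 lower, 11 and 0 adjusted over the list alone (camera adjusted p = 0.000484; adjusted p = 0.467 with an estimated correlation). Kdr, a receptor of vascular growth factor, stood at 12.4 ± 1.26 FPKM in HFD_PA1 and 8.17 ± 0.419 in HFD_PA0.25, called with all libraries but not without HFD_PA0.25 library 0 (adjusted p = 0.0685) or HFD_PA1 library 0 (0.116). Female-biased genes were higher, with 4 of 6 tested members higher and 0 lower, 4 and 1 adjusted over the list alone (camera adjusted p = 0.00593; adjusted p = 0.335 with an estimated correlation) and a median of 0.77. Acot3, an acyl-CoA thioesterase gene, was called higher, at 15.2 ± 1.54 against 7.45 ± 0.0586 FPKM. This call was lost over loci naming 1 protein-coding gene (adjusted p = 0.0981, median 0.60) and with the trend on transcript length and GC content removed (0.179, median 0.60), in a range of 0.00294 to 0.179. Fatty acid synthesis genes were lower on balance, with 2 of 19 tested members higher and 4 lower, 2 and 6 adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.707 with an estimated correlation). Acacb, an acetyl-CoA carboxylase, was called lower, at 2.41 ± 0.166 against 4.64 ± 0.338 FPKM. The fatty acid synthesis call was lost without HFD_PA0.25 library 0 (adjusted p = 0.0916) and HFD_PA1 library 0 (0.0668), in a range of 0.000327 to 0.0916.

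Fatty acid oxidation genes were higher on balance at the higher level, against the lower Fgf21, with 10 of 27 tested members higher and 4 lower, 14 and 4 adjusted over the list alone (camera adjusted p = 0.0435; adjusted p = 0.707 with an estimated correlation). Cpt1a, the gate of mitochondrial fatty acid entry, was called higher, at 102 ± 6.902 against 68.7 ± 0.739 FPKM, and the pantetheinase gene Vnn1 at 43.7 ± 6.79 against 26.5 ± 1.61. This call was lost without HFD library 0 (adjusted p = 0.0526), HFD library 1 (0.0521), HFD_PA0.25 library 0 (0.0589), HFD_PA0.25 library 1 (0.0803) and HFD_PA1 library 0 (0.113). It was also lost without the trend in the test (0.0882), with unnamed loci (0.0576) and over loci naming 1 protein-coding gene (0.058), in a range of 0.0101 to 0.113. NRF2 and antioxidant genes were lower on balance, with 4 of 23 tested members higher and 9 lower, 4 and 10 adjusted over the list alone (camera adjusted p = 0.0435; adjusted p = 0.614 with an estimated correlation). Gstm1 and Gstm3 were called lower, at 1389.9 ± 86.9 against 2992 ± 166 and 52.3 ± 3.13 against 92.5 ± 4.25 FPKM, whereas Mt2 was called higher, at 36.8 ± 1.32 against 18.4 ± 0.817. The NRF2 call was lost without HFD library 0 (adjusted p = 0.0526), HFD library 1 (0.0521) and HFD_PA0.25 library 1 (0.0906), and under 7 other alternatives from 0.0502 to 0.129, in a range of 0.0221 to 0.129.

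Lists that did not pass between the PA levels still held called genes. G6pc and Pck1, of glucose production, were called lower in HFD_PA1, at 40.6 ± 1.83 against 85.3 ± 7.497 and 441 ± 35.1 against 650.3 ± 16.2 FPKM (glucose list, adjusted p = 0.636). Cholesterol synthesis did not pass (0.165). The sterol exporters Abcg5 and Abcg8 were called higher, at 78.5 ± 1.94 against 48.6 ± 1.03 and 61.4 ± 2.01 against 36.4 ± 1.95 (bile acid list, 0.636). Marco was called lower, at 8.12 ± 0.326 against 28.5 ± 3.16 FPKM (macrophage list, 0.496). Socs2, a target of growth hormone signals outside the lists, was called lower, at 2.300 ± 1.03 against 12.1 ± 0.535 FPKM. Lipid droplets (adjusted p = 0.717), xenobiotic metabolism (0.0865) and endoplasmic reticulum stress (0.218) did not pass. Nor did male-biased genes (0.308), cell cycle (0.115), immediate early genes (0.297), extracellular matrix (0.577), lymphocyte (0.132), bile duct (0.218), erythroid and neutrophil (0.77) and adipose markers (0.218). Cell cycle passed with a filter at any value above 0 (camera adjusted p = 0.00197) and xenobiotic metabolism with the length and GC trend removed (0.0492). Xenobiotic metabolism passed without NF library 0 (0.0491), NF library 1 (0.049) or HFD_PA1 library 1 (0.025), higher in HFD_PA1, and immediate early genes passed without HFD_PA1 library 1 (0.0471), lower. Signs differed for lipid droplets (median 0.02, mean 0.00, test lower), glucose (0.06, -0.11, lower), immediate early (0.05, -0.12, lower), macrophage (0.04, -0.07, lower), erythroid and neutrophil (0.06, -0.06, lower) and male-biased genes (-0.06, 0.05, lower).

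Between HFD_PA1 and HFD_PA0.25, 1877 genes passed in limma, 1038 higher and 839 lower at the higher level; 3578 had an unadjusted p under 0.05. Over 2-fold were 40 higher and 52 lower, and 61.3% of tested genes did not overlap against 33.3% by chance. The count was 932 without HFD_PA0.25 library 0, 548 without HFD_PA1 library 0 and 951 without HFD_PA1 library 1. With median-ratio scaling 862 were higher and 1206 lower, a share of 41.7% higher against 55.3% in the main test. The median log2 difference of all tested genes was 0.0336, and -0.001 without HFD_PA0.25 library 1. This comparison crosses the split: transcripts under 1500 bases had a median log2 difference of -0.10 and those over 5000 bases 0.13.

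**Figure D1:**
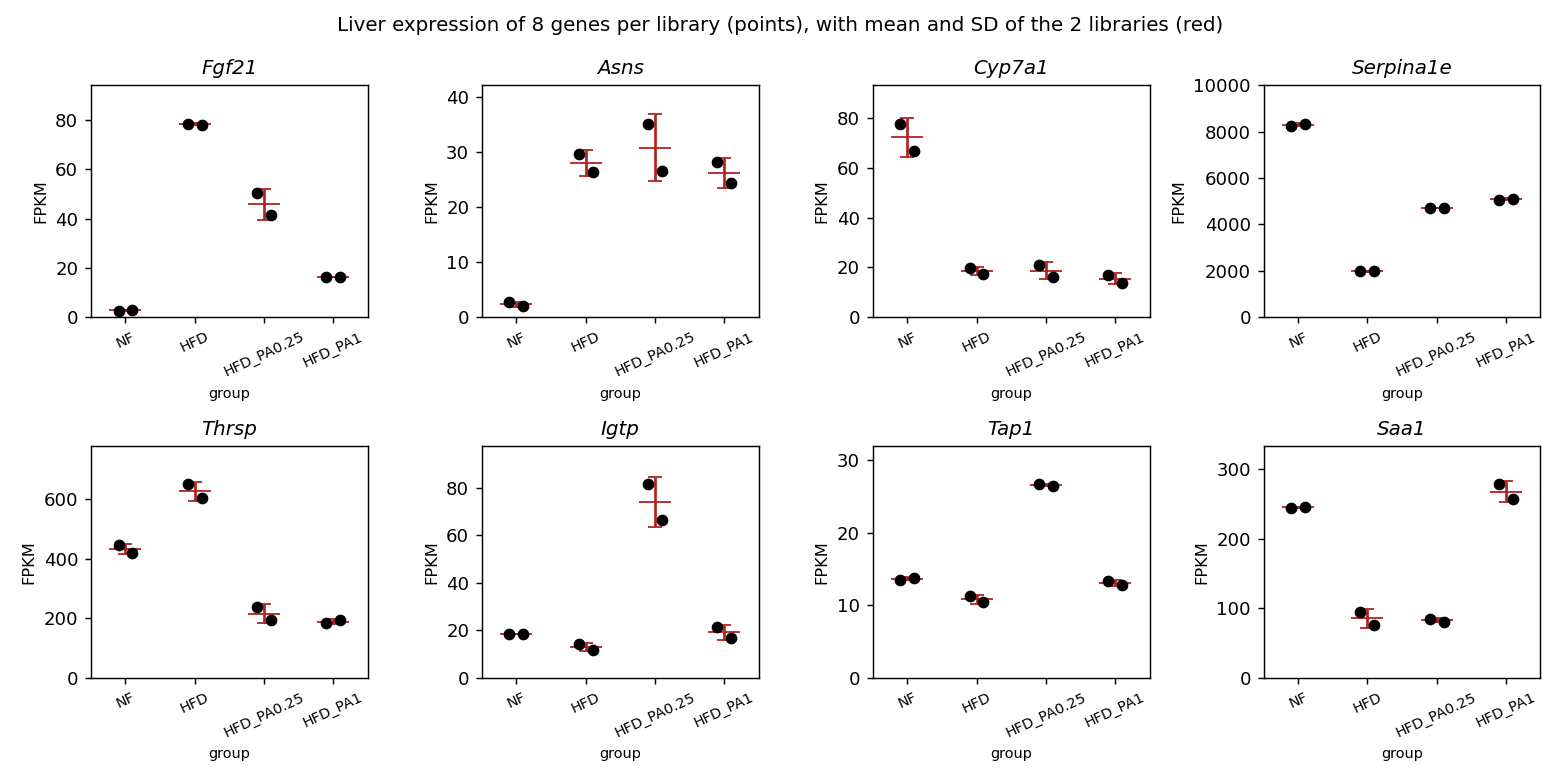
FPKM (y axis) of 8 genes in the NF, HFD, HFD_PA0.25 and HFD_PA1 libraries (x axis), each library as a point and the mean and SD (n = 2) in red. Igtp and Tap1 were highest in HFD_PA0.25 at 73.9 ± 10.5 and 26.6 ± 0.129 FPKM, and Fgf21 was highest in HFD at 78.3 ± 0.431 FPKM.

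**Figure D2:**
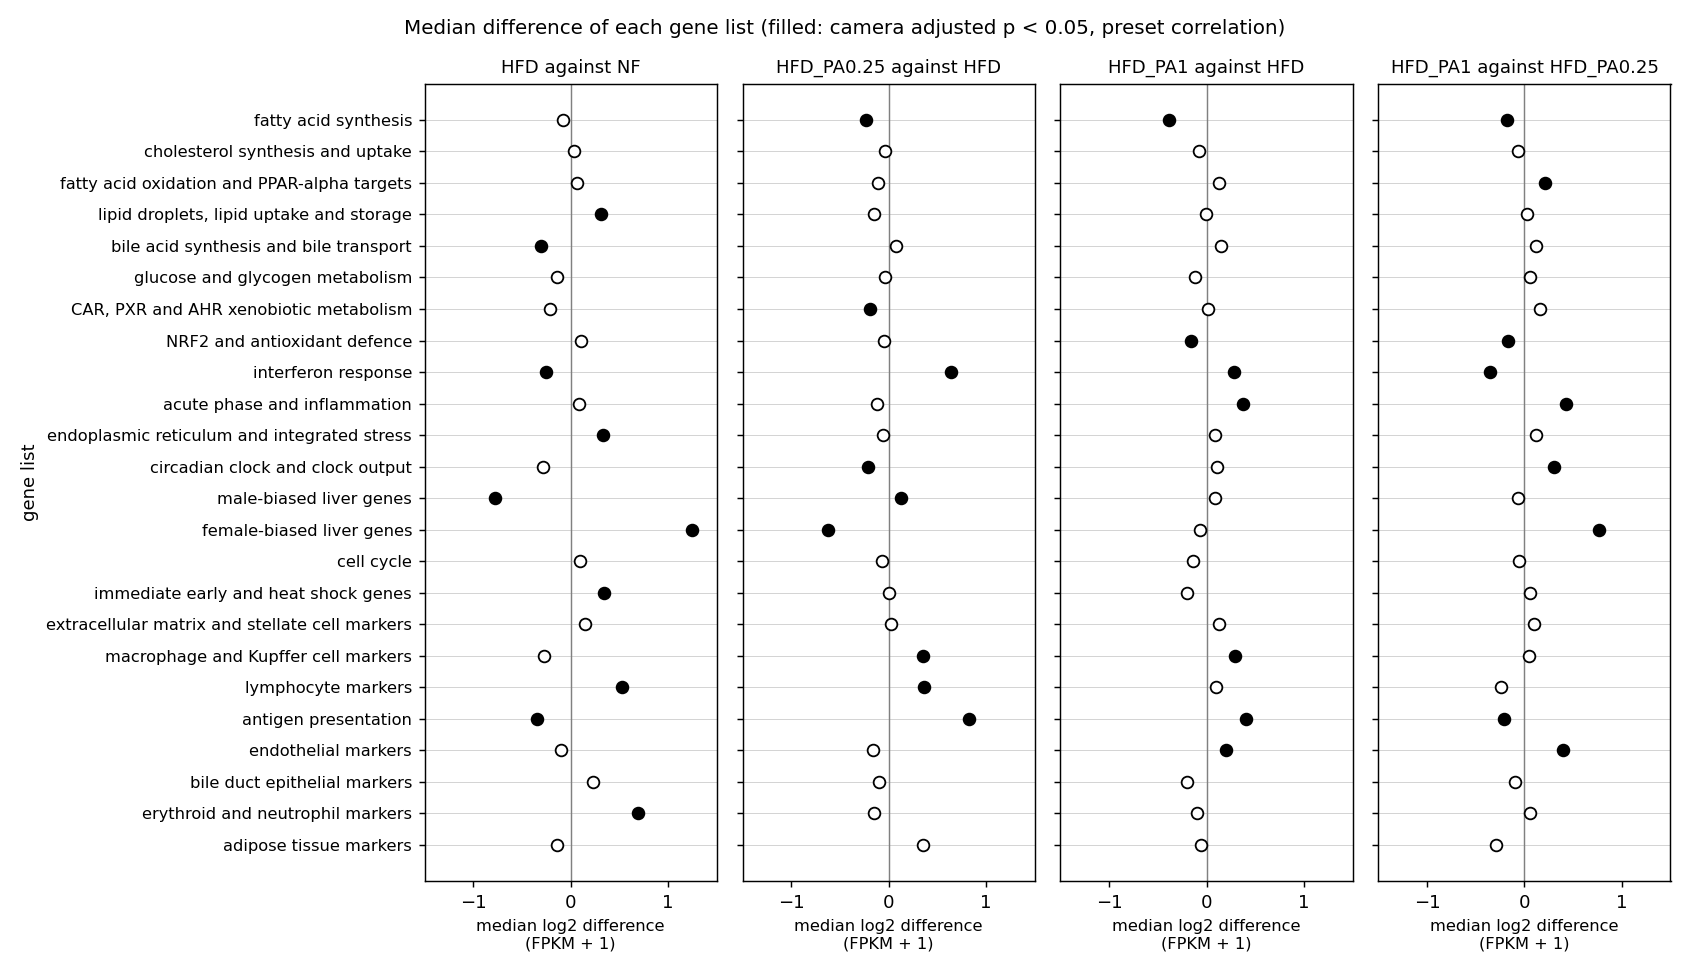
Median log2 difference of FPKM + 1 (x axis) of 24 gene lists (y axis) in 4 comparisons, 1 panel each, with filled points for lists that passed camera with the preset correlation. Male-biased genes lay at -0.78 and female-biased genes at 1.25 in HFD against NF, and antigen presentation genes at 0.82 in HFD_PA0.25 against HFD.

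The PA comparisons were also set beside the diet comparison, to ask how far PA undid the change from NF to HFD. Of the 3496 genes called between HFD and NF, 58.1% had the opposite sign in HFD_PA0.25 against HFD and 88.9% in HFD_PA1 against HFD. Simulated groups with no PA effect gave 50.1% and 50.04%. The 3496 genes were called with HFD libraries that the PA comparisons share, which can raise the share of opposite signs without a PA effect. The transcriptional repressor gene Bcl6, called higher in HFD than in NF and lower in HFD_PA1 than in HFD, stood at 2.62 ± 0.577 FPKM in NF, 21.03 ± 0.8397 in HFD, 11.4 ± 0.0789 in HFD_PA0.25 and 5.13 ± 0.118 in HFD_PA1. Bcl6 is among the 71 genes that separated NF and HFD_PA1 from the other libraries. So are Fgf21, Marco, Saa1, Mup1, Serpina1e, Cidec, Phlda1, Egr1, Nr0b2, Psat1 and Nupr1, named above. Asns stood at 28.05 ± 2.39, 30.9 ± 6.15 and 26.3 ± 2.71 FPKM in the 3 high-fat groups, all above the 2.33 ± 0.475 of NF. Cyp7a1 stood at 18.6 ± 1.66, 18.7 ± 3.39 and 15.4 ± 2.16, all under the 72.2 ± 7.89 of NF. Of the genes higher in HFD than in NF, 416 were lower in HFD_PA1 than in HFD and 17 were higher; of the genes lower in HFD, 522 were higher and 41 lower. For HFD_PA0.25 these counts were 110 and 37, and 122 and 103. The shared HFD libraries favor opposite calls. With 1 HFD library in the diet comparison and the other in the HFD_PA1 comparison, 243 and 225 genes were called in opposite directions (HFD library 0 and 1 in the diet comparison) and 24 and 25 in the same direction. For HFD_PA0.25 these counts were 78 and 79, and 30 and 34.

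Across genes, which are not independent replicates, the log2 differences of HFD_PA0.25 against HFD and of HFD against NF correlated at r = -0.171, or -0.262 without HFD library 0. Those of HFD_PA1 against HFD gave r = -0.587. Both differences contain the HFD libraries with opposite sign, so r is negative without any PA effect. Simulated groups gave -0.149 and -0.144 with the diet effect kept, and the covariance was lower than simulated by -0.00907 and -0.0586. With 1 HFD library in each comparison and none shared, r was -0.0577 and -0.08597 for HFD_PA0.25 and -0.473 and -0.457 for HFD_PA1 (HFD library 0 and 1 in the diet comparison). HFD_PA1 against HFD crosses the split whereas HFD_PA0.25 against HFD does not. The PA levels, each against HFD, shared 85 higher and 112 lower genes, with 17 and 25 called in opposite directions, and their log2 differences had r = 0.313 and a covariance of 0.0211. Simulated groups that share the HFD libraries and have no effect gave r = 0.501 and a covariance of 0.00771 (SD 0.00128). That SD holds for genes drawn independently. With no HFD library shared r was 0.1905 and 0.122, and 48 and 49 genes were called in the same direction and 8 and 6 in opposite directions (HFD library 0 and 1 in the HFD_PA0.25 comparison).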

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

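The tests of library preparation or sequencing, of shared reads, of a return toward NF, and of a larger share of macrophages and lymphocytes were chosen only after the results were seen. The difference between the PA effects was tested directly, as HFD_PA1 against HFD_PA0.25, and 9 lists passed camera with the preset correlation; none (0) passed with an estimated correlation, where 1 had an unadjusted p under 0.05. Their median log2 differences, HFD_PA1 minus HFD_PA0.25, were -0.18 for fatty acid synthesis (-0.06 and -0.33 without HFD_PA0.25 library 0 and 1), 0.21 for fatty acid oxidation, -0.17 for NRF2 (-0.08 without HFD_PA0.25 library 1 and -0.10 without HFD_PA1 library 0), -0.35 for interferon response and 0.42 for acute phase genes. They were 0.31 for clock genes, 0.77 for female-biased genes, -0.21 for antigen presentation and 0.39 for endothelial markers. This comparison crosses the split between the libraries, so for most of these lists a batch cannot be told apart from the PA level. For interferon response and antigen presentation genes a batch along the split alone is argued against. Both lists were lower in HFD_PA1 than in HFD_PA0.25 but higher in HFD_PA1 than in HFD. Both were also higher in HFD_PA0.25 than in HFD, within the split, at a median of 0.64 for interferon response. Clock and female-biased genes were lower in HFD_PA0.25 than in HFD, within the split, where a batch along it alone gives no difference. Neither of these lists passed in HFD_PA1 against HFD, which crosses it. A batch added to a PA effect common to both levels was not tested for any list. Outside the tested genes, loci without a symbol held 21.5% of the summed FPKM in HFD_PA1, above the 13.4% and 15.3% of the HFD libraries.

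NF and HFD_PA1 libraries stood apart from HFD and HFD_PA0.25 libraries, and HFD_PA1 against HFD ran against the diet change at r = -0.587. A trend with transcript length and GC content is argued against as the whole of it: with that trend removed r was -0.589, against -0.154 in groups simulated from the same values with no PA effect. Reads shared between near-identical copies are argued against likewise, since over 3248 genes that share no 30-base word with the transcripts of another gene r was -0.589, against -0.161 simulated over those genes. A difference in library preparation or sequencing may be part of it. The FPKM step at 160-base loci was at least 3.88 times higher in NF and HFD_PA1 libraries than in the others. For the lowest values of olfactory, vomeronasal and taste receptor genes of about 1 kb the ratio was 0.901. Only 2 to 6 of these 1113 genes were above 0 in a library. The step was among the measures that showed the split, so it is no independent test of this cause. A return of HFD_PA1 livers toward NF cannot be told apart from such a batch, because r = -0.587 comes from a comparison that crosses the split and none within it tests the return.

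Interferon response and antigen presentation genes were higher in HFD_PA0.25 than in HFD, within the split. A trend with transcript length and GC content is argued against by its small size in this comparison. The log2 differences had rank correlations of 0.0871 with length and 0.0355 with GC content. With so little trend to remove, the median of 0.64 that the interferon list kept without it adds little. A larger share of macrophages and lymphocytes cannot be told apart from a response: the median of the interferon list lay 0.28 above that of 23 macrophage and lymphocyte markers (bootstrap SE 0.128; median of the markers 0.35), but 0.24 (0.153) without HFD library 1, 0.28 (0.147) without HFD_PA0.25 library 0 and 0.43 (0.132) without HFD_PA0.25 library 1. Among the most abundant markers, C1qa stood at 81.1 ± 9.51 FPKM in HFD and 117 ± 10.1 in HFD_PA0.25, and no sort of cells preceded extraction. A response to the diet with 0.25% PA, or to an immune stimulus in those mice, may be behind it, and neither was tested.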

How the results depend on the processing

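Alternatives chosen after the data were seen are those on unnamed loci, genes at 0, protein-coding loci, the length and GC trend, a different HFD library in each comparison, and genes without shared words. No called result reversed under any alternative. Of the list results under the alternatives, 2600 kept their direction and side of the threshold, 112 lost their call, 63 gained a call and 63 not called changed sign. These list results take in the estimated correlation, under which every called list lost its call. The ranges of adjusted p given above leave that setting out. Of the named genes 11206 kept theirs, 667 lost and 116 gained a call, and 8 not called changed sign. The estimated correlation left 0 lists called by camera in each of the 4 planned comparisons. There 3, 3, 2 and 1 lists had an unadjusted p under 0.05. How much of this loss came from correlated members was not tested. Leaving out each library in turn gave 1857 to 3570 genes for HFD against NF, 217 to 694 for HFD_PA0.25 against HFD, 227 to 1409 for HFD_PA1 against HFD and 548 to 1989 for HFD_PA1 against HFD_PA0.25. A group then has 1 library, assumed to vary like the other groups. The correlation with the diet change ranged from -0.262 to -0.139 for HFD_PA0.25 and from -0.621 to -0.542 for HFD_PA1 without single libraries. It was -0.524 for HFD_PA1 with unnamed loci, -0.612 without genes at 0 and -0.622 over loci naming 1 protein-coding gene. The settings with -0.612 and -0.622 leave out the joined Apoe and Tomm40 locus, and what caused these shifts was not tested. With no HFD library shared it was -0.0577 and -0.08597 for HFD_PA0.25 and -0.473 and -0.457 for HFD_PA1, since the shared libraries push it below 0. By changing which genes are tested, a filter at any value above 0 gave 372 genes for HFD_PA0.25 and 749 for HFD_PA1, each against HFD, and a filter at 5 FPKM left 6 lists for HFD against NF. With only the libraries compared, HFD_PA0.25 against HFD gave 427 genes, in a fit with fewer libraries. No paired analysis was possible because nothing ties a library of one group to a library of another. What depth limits was not tested, because read counts were not used here.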

Other observations

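The comparison of HFD_PA1 with NF lies within the split. It was chosen only after the data were seen, as were the tests of gene families and of STAT5 targets. Lying within the split does not make these groups alike. Loci without a symbol held more of the summed FPKM in NF, and the groups lay apart on the first principal component. The rank correlation of the log2 differences with GC content was 0.212, against 0.294 in HFD against NF and -0.193 in HFD_PA1 against HFD, which both cross the split. Livers of HFD_PA1 mice differed from those of NF mice in stress, acute phase and lipid genes. Genes of endoplasmic reticulum and integrated stress were higher, with 13 of 18 tested members higher and 0 lower, 14 and 0 adjusted over the list alone (camera adjusted p = 5.93e-12; adjusted p = 0.125 with an estimated correlation). Asns stood at 26.3 ± 2.71 FPKM in HFD_PA1 and 2.33 ± 0.475 in NF (log2 difference 3.04, adjusted p = 1.46e-06), and Hspa5, the main chaperone of the reticulum, at 217 ± 13.6 and 132 ± 8.36 (log2 difference 0.71, adjusted p = 0.00123). Acute phase genes were higher, with 10 of 21 tested members higher and 0 lower, 13 and 1 adjusted over the list alone (camera adjusted p = 1.44e-06; adjusted p = 0.372 with an estimated correlation); Lcn2, an iron-scavenging lipocalin, stood at 12.9 ± 2.41 and 3.18 ± 1.42 FPKM (log2 difference 1.77, adjusted p = 0.00454). Neutrophils express Lcn2 too, and the neutrophil genes S100a8 and S100a9 stood at 33.8 ± 5.49 and 17.5 ± 1.97 FPKM in HFD_PA1 and 8.65 ± 1.01 and 3.12 ± 0.357 in NF, so their share is not separated from the acute phase. Lymphocyte markers were higher, with 3 of 6 tested members higher and 0 lower, 4 and 0 adjusted over the list alone (camera adjusted p = 0.000656; adjusted p = 0.187 with an estimated correlation), and Jchain stood at 15.4 ± 1.53 and 3.296 ± 0.478 FPKM. Fatty acid oxidation genes were higher on balance, with 4 of 27 tested members higher and 1 lower, 6 and 1 adjusted over the list alone (camera adjusted p = 0.000461; adjusted p = 0.426 with an estimated correlation); Cyp4a14, a PPAR-alpha target, stood at 212 ± 17.1 and 63.9 ± 11.2 FPKM.

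Fatty acid synthesis genes were lower in HFD_PA1 than in NF, with 1 of 19 tested members higher and 12 lower, 2 and 12 adjusted over the list alone (camera adjusted p = 1.03e-05; adjusted p = 0.426 with an estimated correlation), and Acacb stood at 2.41 ± 0.166 and 6.84 ± 0.119 FPKM (log2 difference -1.20, adjusted p = 2.78e-05). Glucose and glycogen genes were lower on balance, with 1 of 20 tested members higher and 6 lower, 3 and 10 adjusted over the list alone (camera adjusted p = 0.00466; adjusted p = 0.387 with an estimated correlation); G6pc stood at 40.6 ± 1.83 and 112 ± 0.865 FPKM. Xenobiotic metabolism genes were lower on balance, with 1 of 16 tested members higher and 8 lower, 1 and 8 adjusted over the list alone (camera adjusted p = 0.000923; adjusted p = 0.426 with an estimated correlation); Por stood at 146 ± 2.28 and 284 ± 5.97 FPKM. Alas1, the rate-limiting enzyme of heme synthesis, fell from 549 ± 23.4 in NF to 113 ± 2.53 FPKM (log2 difference -2.27, adjusted p = 4.64e-08). NRF2 genes were lower on balance, with 3 of 23 tested members higher and 8 lower, 4 and 9 adjusted over the list alone (camera adjusted p = 0.0247; adjusted p = 0.426 with an estimated correlation), a call lost with a filter at 5 FPKM (adjusted p = 0.0644) and with quantile normalization (0.166), in a range of 0.00714 to 0.166. Male-biased genes were lower, with 0 of 17 tested members higher and 13 lower, 0 and 13 adjusted over the list alone (camera adjusted p = 4.02e-11; adjusted p = 0.125 with an estimated correlation); female-biased genes were higher, with 5 of 6 tested members higher and 0 lower, 5 and 1 adjusted over the list alone (camera adjusted p = 8.84e-08; adjusted p = 0.125 with an estimated correlation). In all, 1277 genes passed in limma, 539 higher and 738 lower, and 57.0% of tested genes did not overlap against 33.3% by chance. With quantile normalization 673 were higher and 639 lower (51.3% higher), against 42.2% in the main test. The count was 695 without NF library 0, 578 without HFD_PA1 library 0 and 544 without HFD_PA1 library 1. HFD_PA0.25 against NF, which crosses the split, gave 4064 genes, 1640 higher and 2424 lower (40.4% higher), and 2491 without NF library 0. With median-ratio scaling 2115 were higher and 2041 lower (50.9% higher), and with quantile normalization 2039 and 2059 (49.8%).

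Male-biased genes were lower and female-biased genes higher in HFD_PA1 than in NF, in male mice; a trend with transcript length and GC content is argued against as the whole of it, since the male-biased list had a median log2 difference of -0.66 with that trend removed. Reads shared within gene families are argued against for 7 male-biased genes with under 5% of their 30-base words in transcripts of another gene: 4 of the 7 were called lower, against 6.71% of 8301 tested genes with as few shared words (exact hypergeometric test, p = 0.000596, over genes that are not independent), although their median of -0.58 (bootstrap SE 0.304) is widely spread. For the 10 others shared reads cannot be told apart from a change in expression, since their median lay -0.30 from that of the 7 (bootstrap SE 0.366). Growth hormone, which sets the sex bias of the liver through STAT5, is a candidate explanation, not tested by hormone levels: 4 of 4 STAT5 targets were called lower, Cish (log2 difference -1.23, adjusted p = 0.000816), Socs2 (log2 difference -1.53, adjusted p = 0.000353), Igf1 (log2 difference -0.46, adjusted p = 0.00311) and Igfals (log2 difference -0.46, adjusted p = 0.00205), also without any 1 library, but 3 of 4 in HFD against NF (4 without HFD_PA1 library 0 or library 1) and in HFD_PA0.25 against NF, where Socs2 stood at 6.04 ± 0.581 and 12.1 ± 0.535 FPKM against 8.27 ± 0.158 in NF. Both of those comparisons cross the split. Socs2 was not called in HFD against NF (log2 difference -0.40, limma adjusted p = 0.1). It was called higher in HFD_PA0.25 against NF (log2 difference 0.50, limma adjusted p = 0.0427), opposite in direction to the other targets. HFD against NF had the sex-biased pattern too, with medians of -0.78 and 1.25. Male-biased genes were lower in HFD_PA0.25 than in NF, with 13 of 17 lower and 3 higher (camera adjusted p = 0.000128, or 0.322 with an estimated correlation). Female-biased genes also passed there, a call lost over loci naming 1 protein-coding gene (0.0756, median 0.549) and with a filter at any value above 0 (0.171, median 0). Neither list passed in HFD_PA1 against HFD (adjusted p = 0.664 and 0.689).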
